A study of Mus musculus with 18 samples.

How the data were processed

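RNA-seq of nuclear and total RNA was measured in 18 mouse libraries, 3 in each of 6 groups (2 RNA fractions by 3 Nup93 genotypes). RNA was extracted with TRIzol and libraries were made with the KAPA Stranded mRNA-Seq kit, per the labels' protocols. CASAVA, STAR 2.5.2b, featureCounts and DESeq2 are named together with the mouse build mm9, per the submitters' processing notes, which give no order or settings. The annotation and the strand setting of the counting are not stated, which leaves overlapping antisense pairs such as Xist and Tsix uncertain. The authors deposited 1 table of raw, unnormalised counts per gene symbol, with a gene length column that was not used here. All 18 count columns were used, and groups were taken from the sample names and genotype labels.

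The deposited counts of Total_WT replicate 1 summed to 200140709, 10.2 times the mean of the other 17 libraries. Of its genes 0 lay below the gene-by-gene sum of the 9 nuclear columns, which is 181106189. The remainder after subtracting that sum, 19034520 counts, was used for this library, and this step was chosen after seeing the data. The median chi-square between this library and replicates 2 and 3, relative to sampling noise, was 6.04 and 6.03 for the deposited column and 1.49 and 1.34 for the remainder, beside 1.51 between replicates 2 and 3. Total_Hom replicate 2 stood at 4.84 against each of the other 2 Total_Hom libraries, so this measure also varies between columns of ordinary depth. Depth after this step was 17.4 to 23.5 M (mega) counts per library, and 4177 genes had no count in any library. Reads carry no molecular identifiers, so limits from counts cover counting error only.

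Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM factors, robust quasi-likelihood fits (glmQLFit) and glmQLFTest, with Benjamini-Hochberg (BH) adjusted p under 0.05 as the threshold. The 9 libraries of a fraction formed 1 fit for the genotype comparisons (15112 nuclear and 15051 total genes tested). All 18 formed 1 fit (15410 genes) for the nuclear-to-total ratio of Hom or Het relative to WT, an interaction term, and for nuclear against total RNA in WT. The biological coefficient of variation was 3.05% in nuclear, 3.90% in total and 3.54% in all libraries. CPM values are means of the 3 libraries with their SD, scaled by TMM-adjusted sizes of all 18 libraries. Errors of log2 values are SE from the fits.

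Genes were named by a fixed rule. Nup93 was named in every comparison. Among called genes with a mean of at least 5 CPM and groups that do not overlap, the 10 largest rises and falls were named for Hom against WT in each fraction and in the ratio, and the 5 largest elsewhere. Up to 4 members with the smallest p were named per gene list, and predicted gene models were counted but not named. For nuclear against total RNA, Malat1, Neat1, Xist and Meg3 were named as well. Some genes that met the rule are not reported here.

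The 37 fixed gene lists covered cell types (podocyte, mesangial, endothelial, proximal tubule, distal nephron, parietal, immune, erythroid), sex-linked genes, nuclear pore, transport, RNA processing and nuclear-retained RNAs, and stress, metabolic and signalling pathways. The mitochondrially encoded list had no measured member, so 36 were tested. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, BH adjusted within a comparison. Camera with an estimated correlation and fry were alternatives, and fry asks only whether a list moves 1 way, not whether it differs from other genes. Calls of list members were counted over all genes and adjusted over the list alone. Lists overlap, for example C3 in the complement and NF-kB lists.

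Tests on simulated counts with known changes in 50 genes per fold recovered 14%, 72%, 94% and 100% of changes of 1.1, 1.5, 2 and 4-fold in nuclear Hom against WT, with 8 of 14732 unchanged genes called. In total RNA 10%, 84%, 98% and 100% were recovered (3 of 14703 unchanged genes called), and in the ratio 4%, 74%, 82% and 96% (8 of 14961). Far fewer genes were changed in these simulations than were called in the data (8213 of 15112 in nuclear Hom against WT). The adjusted threshold was therefore stricter in the simulations, and their recovery does not give the sensitivity for the data. A simulated list of 20 genes shifted by 1.2-fold was called, as was 1 of the other lists.

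Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no low-count filter, a mean of at least 5 CPM, replicate number as a block, only the groups compared, all 18 libraries in 1 fit, Spearman correlation, and leaving out each library. The deposited column of Total_WT replicate 1 and removal of Rn45s were alternatives added after seeing the data. Correlations of the Het and Hom changes were set beside the mean of 20 simulations of unchanged groups that share their WT libraries. Neighbours of Nup93 were taken from the gene order of GRCm38, 100 each side. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.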

Results

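Gene-level read counts from RNA-seq were examined in 18 mouse libraries, 3 in each of 6 groups. The groups combined 2 RNA fractions, nuclear and total, with 3 Nup93 genotypes. The genotypes were wild type (WT), heterozygous for the R388W allele (Het) and homozygous for it (Hom). Nup93 is a structural component of the nuclear pore. The sample labels named the material only as mouse tissue, while the series text named isolated podocytes, the filtering epithelial cells of the glomerulus. Libraries held 17.4 to 23.5 M (mega) counts as used here. In each library 17248 to 18021 genes had at least 1 count. The column of Total_WT replicate 1 held 200140709 counts, and 0 of its genes lay below the sum of the 9 nuclear columns. That sum was therefore subtracted, a choice made after seeing the data. The remaining 19034520 counts were used for this library. Nothing in the labels said that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The comparisons, the thresholds, the rule for naming genes and the gene lists were set before the data were examined.

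Transcripts of kidney tubules were among the most abundant. Gpx3, a plasma glutathione peroxidase made by proximal tubule cells, averaged 18058 CPM (counts scaled to a common library size) over the 18 libraries. Kap, the androgen-regulated kidney protein of the proximal tubule, averaged 8051 CPM, and Umod, the uromodulin of the thick ascending limb, 5532 CPM. Transcripts not particular to tubules, such as Rn45s (6838 CPM) and Eef1a1 (5551 CPM), also lay above Umod. Proximal tubule markers took 6.70% ± 0.0629 (SD, n = 3) of the counts in Nuclear_WT, 4.70% in Nuclear_Het, 5.10% in Nuclear_Hom, 4.77% in Total_WT, 7.30% in Total_Het and 4.61% in Total_Hom. Podocyte markers took between 0.175% (Total_Het) and 0.254% (Total_WT) of the counts. Immune cell markers took 0.286% in Nuclear_Het and between 0.0948% and 0.180% in the other 5 groups. Rn45s, the ribosomal RNA precursor, took 7.12% of the counts in Total_Hom replicate 2, the highest share in any library, and the lowest share was 0.11%.

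Xist and the Y-linked genes split the groups in a way that crossed both fraction and genotype. Xist, the noncoding RNA that coats the inactive X chromosome, stood at 515 ± 25.5 CPM (SD, n = 3) in Nuclear_Het, 504 ± 10.8 CPM in Nuclear_Hom and 345 ± 10.6 CPM in Total_WT. In Nuclear_WT, Total_Het and Total_Hom it stood at 0.54 ± 0.20, 0.624 ± 0.485 and 1.25 ± 0.368 CPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together showed the opposite. They summed to 163 ± 2.44 CPM in Nuclear_WT, 155 ± 4.2 CPM in Total_Het and 160 ± 4.24 CPM in Total_Hom. The other groups had 2.58 ± 0.315 CPM in Nuclear_Het, 0.610 ± 0.122 CPM in Nuclear_Hom and 0.704 ± 0.224 CPM in Total_WT. Every comparison of Hom or Het with WT, and that of nuclear with total RNA in WT, therefore set libraries with high Xist against libraries with low Xist. Only Hom against Het, in either fraction, did not. Within each genotype the nuclear and total libraries also differed in Xist status, so if the labels hold they came from different animals.

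**Figure D1:**
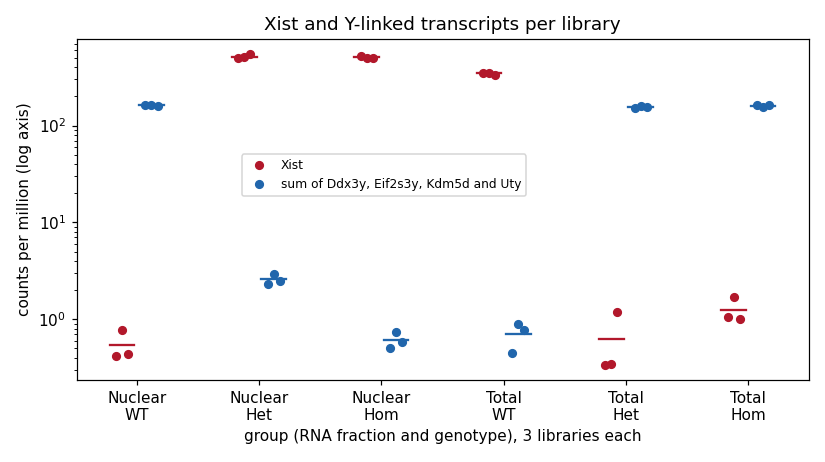
CPM (log axis) of Xist and of the summed Y-linked genes in each of the 18 libraries, 3 per group, with a line at each group mean. Nuclear_Het, Nuclear_Hom and Total_WT had high Xist (515, 504 and 345 CPM), and Nuclear_WT, Total_Het and Total_Hom had high Y-linked counts (163, 155 and 160 CPM).

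Nup93 itself was measured at 15.9 ± 0.864 CPM (SD, n = 3) in Nuclear_WT, 22.5 ± 0.873 in Nuclear_Het and 20.2 ± 1.87 in Nuclear_Hom, and at 20.7 ± 0.182, 19.2 ± 0.460 and 21.2 ± 0.624 CPM in Total_WT, Total_Het and Total_Hom. In nuclear RNA it was higher in Hom than in WT (log2 0.35 ± 0.07 SE, edgeR adjusted p = 2.43e-05) and higher in Het than in WT (log2 0.51 ± 0.07, edgeR adjusted p = 1.53e-09). It was lower in nuclear RNA of Hom than of Het (log2 -0.16 ± 0.07, edgeR adjusted p = 0.0470). That call was lost with DESeq2 (-0.16), RLE size factors (-0.15) and no low-count filter (-0.15). It was also lost without Nuclear_Het replicate 1 (-0.17) or 3 (-0.13) and without Nuclear_Hom replicate 1 (-0.13) or 3 (-0.12), and the value was -0.24 without Nuclear_Hom replicate 2. Total RNA gave log2 values of 0.03 for Hom against WT (edgeR adjusted p = 0.697), -0.11 for Het against WT (0.173) and 0.14 for Hom against Het (0.0660), none of which passed the test. With library totals alone Nup93 passed in total Het against WT (log2 -0.29) and in total Hom against Het (0.30). The latter also passed at a mean of at least 5 CPM (0.18) and without Total_Hom replicate 3 (0.17). A point variant need not change the level of its own transcript, so these values do not check the genotype labels.

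Nuclear and total RNA of WT were compared to see how the fractions differ without the mutant allele. The nuclear libraries of WT held more proximal tubule transcripts and fewer immune and endothelial ones. Among 20 proximal tubule markers 17 were higher and 2 lower in nuclear RNA, in the same numbers adjusted over the list alone (median log2 0.41, camera adjusted p = 1.08e-07). Cyp4b1 (log2 3.39 ± 0.02), Acsm2 (2.06 ± 0.02) and the organic anion transporter Slc22a6 (1.54 ± 0.02) were among them. Of 19 endothelial markers 18 were lower and none (0) higher, also adjusted over the list alone (median log2 -0.53, camera adjusted p = 4.30e-10), for example Eng (log2 -0.79 ± 0.03) and Flt1 (log2 -0.84 ± 0.04). Of 22 immune cell markers 20 were lower and 1 higher, again adjusted over the list alone (median log2 -0.99, camera adjusted p = 7.63e-10), led by lysozyme 2 (Lyz2, log2 -1.89 ± 0.04). These 3 calls held with an estimated correlation (adjusted p = 0.00603, 0.000393 and 0.00257). Nuclear_WT had low and Total_WT high Xist, so fraction was not separable from sex here. In Het the proximal tubule share was lower in nuclear than in total RNA (4.70% and 7.30%) and the immune share higher (0.286% and 0.163%). In Hom both shares differed as in WT (5.10% and 4.61%, and 0.0948% and 0.180%).

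Nuclear-retained RNAs, a list of noncoding and some protein-coding transcripts, were not called higher as a group in the nuclear libraries of WT. Malat1, a transcript of nuclear speckles, was at 1745 ± 52.4 CPM (SD, n = 3) in nuclear and 2312 ± 93.8 CPM in total RNA (log2 -0.42 ± 0.06, edgeR adjusted p = 5.21e-05). Neat1, the scaffold of paraspeckles, was at 579 ± 4.79 and 634 ± 13.5 CPM (log2 -0.14 ± 0.02, edgeR adjusted p = 4.97e-10). Meg3 gave a log2 value of 0.59 ± 0.29 that did not pass (edgeR adjusted p = 0.0710). Of 27 nuclear-retained RNAs 9 were higher and 7 lower, in the same numbers adjusted over the list alone (camera adjusted p = 0.925), with a median of 0.12 (-0.04 with library totals alone) and a mean of -0.24 on the log2 scale. The list includes Xist (log2 -9.33), low in Nuclear_WT and high in Total_WT, which pulls the mean down. Mitochondrially encoded genes were not among the symbols tested. In all, 4769 genes were higher and 4746 lower in nuclear RNA of WT, 372 and 1124 of them by at least 2-fold. Scaling by library totals alone shifted the median log2 value of all genes by -0.16 and the share of higher calls from 50.1% to 25.4%.

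The comparison of Hom with WT in nuclear RNA asked which transcripts change in the nucleus when both Nup93 copies carry the variant. Slco1a1, Cyp7b1 and Slc7a13 fell to a small part of their WT level. Slco1a1, an organic anion transporter, went from 239 ± 4.16 to 0.446 ± 0.121 CPM (SD, n = 3; log2 -9.06 ± 0.08 SE, edgeR adjusted p = 4.60e-92). Cyp7b1, an oxysterol hydroxylase, went from 338 ± 4.28 to 3.30 ± 0.408 CPM (log2 -6.68 ± 0.05), and the amino acid transporter Slc7a13 from 758 ± 19.4 to 8.42 ± 0.976 CPM (log2 -6.49 ± 0.04). Hdc, which makes histamine, rose from 1.98 ± 0.159 to 138 ± 1.59 CPM (log2 6.13 ± 0.07, edgeR adjusted p = 6.24e-84), and the growth factor Igf2 from 14.2 ± 0.683 to 256 ± 16.0 CPM (log2 4.17 ± 0.05). The genes of this paragraph followed Xist status over all groups, so these changes were not separable from sex. Slco1a1, for example, stood at 720 CPM in Total_Het and 47.3 CPM in Total_Hom, but at 10.4 CPM in Nuclear_Het and 1.17 CPM in Total_WT.

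The 10 largest rises among genes of at least 5 CPM in nuclear Hom against WT were those of Xist (log2 9.88), Ugt1a2 (6.96), Slc17a2 (6.16), Hdc, Rdh19 (5.24), Cyp4a14 (5.10), Akr1c20 (4.73), Fabp1 (4.58), Atp13a4 (4.31) and Igf2. Ugt1a2 shares its 3' exons with the other Ugt1a genes, so its counts are uncertain. The largest falls were those of Slco1a1, the Y-linked Uty (log2 -8.83), Ddx3y (-7.93) and Eif2s3y (-7.64), Cyp2j13 (-7.47), Pzp (-7.18), Cyp7b1, Slc7a13 and Ugt2b37 (-6.40). Kdm5d was also among the falls, but its Nuclear_Hom libraries held 3 counts in all, so its fitted fold depends on the prior count. Uty held 4 counts there, so its fold leans on the prior count too. Nuclear_Hom had high and Nuclear_WT low Xist.

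Ribosomal protein genes rose as a group in nuclear Hom, with 76 of 82 higher and 1 lower, also adjusted over the list alone (median log2 0.41, camera adjusted p = 1.15e-29), for example Rpl13a (log2 0.51 ± 0.02) and Rps3 (0.47 ± 0.02). The call was lost when the correlation was estimated (adjusted p = 0.151 with an estimated correlation). Heat shock genes, which encode protein chaperones, fell in 16 of 20 members and none (0) rose, or 16 and 1 adjusted over the list alone (median log2 -0.53, camera adjusted p = 1.12e-10, adjusted p = 0.0104 with an estimated correlation). Hspa8 (log2 -0.92 ± 0.02), Dnaja1 (-0.96 ± 0.03) and Hsp90ab1 (-0.57 ± 0.02) led this list. Cholesterol synthesis and uptake genes fell in 16 of 24 members with none (0) higher, also adjusted over the list alone (median log2 -0.28, camera adjusted p = 9.22e-07, adjusted p = 0.0179 with an estimated correlation). They included Sqle (log2 -1.28 ± 0.03) and Idi1 (-1.57 ± 0.06). These 2 lists were the only calls in nuclear Hom that held with an estimated correlation.

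Inflammatory and stromal lists were called higher in nuclear Hom. Complement and antigen presentation genes had 15 of 23 members higher and 3 lower, also adjusted over the list alone (median log2 0.30, camera adjusted p = 0.000744, adjusted p = 0.0903 with an estimated correlation), with C3 at log2 3.20 ± 0.04 but Cd74 at log2 -0.46 ± 0.02. NF-kB and cytokine genes, which also count C3, had 13 of 25 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00696, adjusted p = 0.0895 with an estimated correlation). Immune cell markers had 12 of 22 higher and 2 lower, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.180 with an estimated correlation). Their summed share of the counts did not rise (0.0959% in Nuclear_WT and 0.0948% in Nuclear_Hom), and H2-Ab1 (log2 -0.59 ± 0.03) and Cd74 fell. In the same order, endothelial, mesangial and parietal epithelial markers had 12 of 19, 10 of 17 and 7 of 14 members higher and 2, 1 and 1 lower, or 12, 10 and 7 higher and 2, 2 and 1 lower adjusted over the list alone (camera adjusted p = 0.0114, 0.0311 and 0.0434). Their calls were lost when the correlation was estimated (adjusted p = 0.0903, 0.151 and 0.182 with an estimated correlation). Among extracellular matrix genes 15 of 30 were higher and 4 lower, and among senescence-associated secretory genes 13 of 26 were higher and 5 lower, both also adjusted over the list alone (camera adjusted p = 0.0200 and 0.0114, adjusted p = 0.151 and 0.110 with an estimated correlation). Of 25 p53 target genes 15 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.0903 with an estimated correlation), for example the cell cycle inhibitor Cdkn1a (log2 0.79 ± 0.05).

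Lists called lower in nuclear Hom also covered transport through the pore and protein turnover. Nuclear transport receptors and Ran cycle genes had 16 of 29 members lower and 2 higher, also adjusted over the list alone (median log2 -0.12, camera adjusted p = 0.00827), but the median became 0.01 with library totals alone. That call was lost when the correlation was estimated (adjusted p = 0.110 with an estimated correlation). Rangap1 (log2 -0.51 ± 0.04), Kpna4 (-0.48 ± 0.04) and Tnpo1 (-0.37 ± 0.04) were its examples. Unfolded protein response genes had 20 of 32 lower and 8 higher, or 20 and 9 adjusted over the list alone (camera adjusted p = 0.00390, adjusted p = 0.0895 with an estimated correlation), with the chaperone Hspa5 at log2 -0.80 ± 0.02. Autophagy and lysosome genes had 22 of 34 lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.000744, adjusted p = 0.151 with an estimated correlation). Proximal tubule markers had 12 of 20 lower and 6 higher, also adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.207 with an estimated correlation). The sex-linked list had 4 of 5 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.000498, adjusted p = 0.0895 with an estimated correlation).

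Podocyte, nucleoporin and RNA processing lists did not pass in nuclear Hom. Podocyte markers had 13 of 30 higher and 5 lower (camera adjusted p = 0.296) and slit diaphragm and basement membrane genes 5 of 22 higher and 8 lower (0.757). Nucleoporins had 2 of 31 higher and 8 lower (camera adjusted p = 0.560), mRNA export factors 3 of 26 higher and 5 lower (0.933), splicing factors 5 of 37 higher and 10 lower (0.915) and nuclear-retained RNAs 12 of 27 higher and 5 lower (0.175). Among metabolic lists, respiratory chain genes had 16 of 80 higher and 25 lower (camera adjusted p = 0.915), glycolysis genes 7 of 26 higher and 9 lower (0.903), lipid droplet and fatty acid genes 16 of 32 higher and 12 lower (0.147) and NRF2 and oxidative stress genes 9 of 33 higher and 16 lower (0.236). Replication-dependent histones had 5 of 15 higher and 4 lower (camera adjusted p = 0.452), cell cycle genes 4 of 34 higher and 2 lower (0.824), erythroid markers 1 of 5 higher and 2 lower (0.514) and distal nephron markers 8 of 19 higher and 8 lower (0.900). Among signalling lists, actin regulators had 12 of 36 higher and 17 lower (camera adjusted p = 0.666), BMP and SMAD genes 13 of 29 higher and 10 lower (0.245) and YAP and TEAD targets 10 of 23 higher and 9 lower (0.915). Interferon response genes had 8 of 31 higher and 4 lower (camera adjusted p = 0.365) and immediate early genes 14 of 28 higher and 8 lower (0.757). Adjusted over the list alone, podocyte markers had 14 higher and 5 lower, histones 6 and 4, cell cycle genes 3 and 2, actin regulators 13 and 17, BMP and SMAD genes 14 and 10, interferon genes 8 and 3 and lipid genes 17 and 13, while the other lists of this paragraph kept their numbers.

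In all, 8213 of 15112 genes passed in nuclear Hom against WT, 4011 higher and 4202 lower, and 698 and 260 of them changed by at least 2-fold. Scaling by library totals alone shifted the median log2 value of all genes by 0.12 and the share of higher calls from 48.8% to 73.8%.

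Hom was set against WT in total RNA to see whether the cellular pool changed as the nuclear pool did. The genes with the largest changes were mostly those of the nuclear comparison, with the sign turned. Slco1a1 rose from 1.17 ± 0.0696 to 47.3 ± 2.30 CPM (SD, n = 3; log2 5.33 ± 0.06 SE, edgeR adjusted p = 2.42e-121), and Slc7a13 from 6.17 ± 0.580 to 288 ± 2.61 CPM (log2 5.54 ± 0.03). Igf2 fell from 429 ± 4.95 to 5.63 ± 1.03 CPM (log2 -6.25 ± 0.04, edgeR adjusted p = 4.05e-132) and Hdc from 364 ± 7.09 to 9.94 ± 0.426 CPM (log2 -5.19 ± 0.04). Total_Hom had low and Total_WT high Xist, the reverse of the nuclear comparison.

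The 10 largest rises in total Hom were those of Uty (log2 8.32), Ddx3y (7.67), Eif2s3y (7.66), Cyp2j13 (6.61), Slc7a13, Pzp (5.50), Slco1a1, Cyp2d9 (5.16), Kdm5d and Mpped1. The Total_WT libraries held 2 counts of Kdm5d and 1 of Mpped1, so the fitted folds of this pair depend on the prior count. They held 4 counts of Uty, whose fold leans on the prior count too. With the deposited column of Total_WT replicate 1, Uty gave a log2 value of 2.24, Kdm5d 2.14, Mpped1 1.42, Cyp2j13 2.62, Slc7a13 1.82, Pzp 1.70 and Slco1a1 0.76, and none of these 7 passed. The largest falls included those of Xist (log2 -8.09), Slc17a2 (-7.63), Igf2, Hdc, Prlr (-4.43), Akr1c20 (-3.91), Aplnr (-3.69), Aadat (-3.49) and Ube2c (-3.26).

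Ribosomal protein genes rose in total RNA too, with 75 of 82 higher and 1 lower, also adjusted over the list alone (median log2 0.38, camera adjusted p = 1.87e-18, adjusted p = 0.143 with an estimated correlation), for example Rpl17 (log2 0.67 ± 0.02). Nuclear-encoded respiratory chain genes fell in 69 of 80 members and rose in 6, also adjusted over the list alone (median log2 -0.28, camera adjusted p = 2.85e-12, adjusted p = 0.143 with an estimated correlation). The ATP synthase genes Atp5b (log2 -0.36 ± 0.01) and Atp5g1 (-0.61 ± 0.02) were among them. Replication-dependent histone genes, near-identical copies whose reads may be split between them, were lower in 13 of 15 members with none (0) higher, also adjusted over the list alone (median log2 -1.14, camera adjusted p = 0.000142, adjusted p = 0.0845 with an estimated correlation). Heat shock genes were lower in 14 of 20 and higher in 3, also adjusted over the list alone (median log2 -0.26, camera adjusted p = 0.00143, adjusted p = 0.0845 with an estimated correlation), among them Cryab (log2 -0.81 ± 0.02). Cholesterol genes were lower in 14 of 24 and higher in 6, also adjusted over the list alone (camera adjusted p = 0.0323, adjusted p = 0.143 with an estimated correlation), including Cyp51 (log2 -1.77 ± 0.03). Lipid droplet and fatty acid genes were lower in 18 of 32 and higher in 10, also adjusted over the list alone (camera adjusted p = 0.0368, adjusted p = 0.143 with an estimated correlation), including the desaturase Scd1 (log2 -3.03 ± 0.02) and Fasn (-1.77 ± 0.03).

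Endothelial and BMP lists were called higher in total Hom, and matrix and distal nephron lists lower. Endothelial markers were higher in 13 of 19 and lower in 2, also adjusted over the list alone (median log2 0.32, camera adjusted p = 0.00161, adjusted p = 0.0845 with an estimated correlation), such as Egfl7 (log2 0.86 ± 0.03) and Flt1 (0.59 ± 0.03). Podocyte markers had 7 of 30 higher and 13 lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.200), although Synpo rose (log2 0.29 ± 0.04). Extracellular matrix genes were lower in 19 of 30 and higher in 8, also adjusted over the list alone (camera adjusted p = 0.0124, adjusted p = 0.143 with an estimated correlation), with the collagens Col1a2 (log2 -1.22 ± 0.04) and Col3a1 (-1.60 ± 0.06) lower but Ctgf (0.92 ± 0.03) higher. BMP and SMAD genes were higher in 19 of 29 and lower in 5, or 20 and 5 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.117 with an estimated correlation), led by Id3 (log2 1.26 ± 0.04) and Id1 (1.46 ± 0.06). Complement genes were higher in 14 of 23 and lower in 4, also adjusted over the list alone, and immediate early genes were higher in 14 of 27 and lower in 4, also adjusted over the list alone (camera adjusted p = 0.0211 and 0.0328, adjusted p = 0.184 and 0.143 with an estimated correlation). Distal nephron markers were lower in 12 of 19 and higher in 6, also adjusted over the list alone (camera adjusted p = 0.0467, adjusted p = 0.143 with an estimated correlation). The p53 targets had 14 of 25 higher and 3 lower, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.0328, adjusted p = 0.143 with an estimated correlation). Nucleoporins had 4 of 31 higher and 7 lower, or 3 and 6 adjusted over the list alone, and did not pass (camera adjusted p = 0.810).

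No list called in total Hom held with an estimated correlation. In all, 9277 of 15051 genes passed in total Hom against WT, 4606 higher and 4671 lower, and 590 and 513 of them changed by at least 2-fold. With the deposited column of Total_WT replicate 1 the number was 7184, without that library 8668, and without Total_Hom replicate 2, the library rich in Rn45s, 8746.

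**Figure D2:**
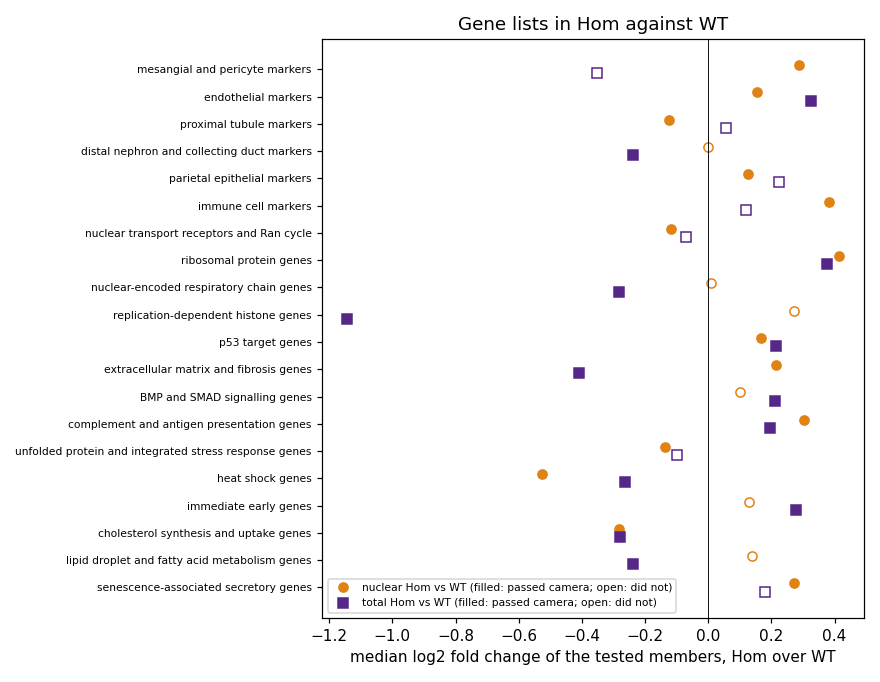
Median log2 fold change, Hom over WT, of the tested members of 20 gene lists that passed camera in nuclear RNA (circles) or total RNA (squares). Filled symbols passed and open ones did not, lists with a member at 3 or fewer summed counts in a group are left out, and with library totals alone the nuclear medians of the nuclear transport and distal nephron lists changed sign. Ribosomal protein genes lay at 0.41 and 0.38 and heat shock genes at -0.53 and -0.26.

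The nuclear-to-total ratio asked whether Hom differed from WT unequally between the fractions, the question raised by a variant in a pore component. Nuclear and total libraries of each genotype differed in Xist status, so if the labels hold they came from different animals. The ratio therefore cannot separate a genotype effect on RNA transport from differences between animals. The respiratory chain, histone, matrix and lipid lists were higher in this ratio, and the sex-linked list lower. Chance cannot be excluded for the number of these calls, since 62 of 100 splits of the same libraries gave at least 5 lists (median of the others 9). Of 80 respiratory chain genes 62 were higher and 5 lower, or 62 and 6 adjusted over the list alone (median log2 0.24, camera adjusted p = 4.21e-08, adjusted p = 0.370 with an estimated correlation), for example Cox6c (log2 0.68 ± 0.03). Replication-dependent histones were higher in 13 of 16 with none (0) lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.000488, adjusted p = 0.110 with an estimated correlation). Extracellular matrix genes were higher in 19 of 30 and lower in 6, and lipid genes higher in 20 of 32 and lower in 9, both also adjusted over the list alone (camera adjusted p = 0.000488 and 0.00977, adjusted p = 0.110 and 0.110 with an estimated correlation). Scd1 (log2 3.85 ± 0.03), Fasn (2.52 ± 0.04) and Col1a2 (1.27 ± 0.06) were higher, while the fatty acid transporter Cd36 (log2 -2.80 ± 0.04) was lower.

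Nup93 rose in this ratio (log2 0.32 ± 0.10, edgeR adjusted p = 0.00297). The largest rises included those of Xist (log2 17.98), Slc17a2 (13.80), Hdc (11.32), Igf2 (10.43), Akr1c20 (8.64), Rdh19 (8.62), Fabp1 (7.75), Prlr (7.56) and Ugt1a2 (7.15). The largest falls were those of the Y-linked Uty (log2 -17.14), Ddx3y (-15.60) and Eif2s3y (-15.30), and of Slco1a1 (-14.38), Cyp2j13 (-14.07), Pzp (-12.67), Slc7a13 (-12.03) and Ugt2b37 (-10.66), together with Kdm5d and Mpped1, whose fitted folds depend on the prior count. Uty held 4 counts in Nuclear_Hom and 4 in Total_WT, and Slc17a2 9 in Nuclear_WT and 7 in Total_Hom, so their folds are uncertain too. In this ratio the sex-linked list had 4 of 5 members lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.000502, adjusted p = 0.110 with an estimated correlation), and it compared high-Xist Nuclear_Hom and Total_WT libraries with low-Xist Nuclear_WT and Total_Hom libraries. Nuclear-retained RNAs had 6 of 27 higher and 11 lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.548), nor did mRNA export factors with 2 of 26 higher and 8 lower, or 2 and 6 adjusted over the list alone (0.544). In all, 8643 of 15410 genes passed, 4378 higher and 4265 lower, and 1216 and 686 of them changed by at least 2-fold. Scaling by library totals alone shifted the median log2 value of all genes by 0.14 and the share of higher calls from 50.7% to 70.4%, while the deposited column of Total_WT replicate 1 gave 7234 genes and 3 lists.

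Genes that changed by at least 2-fold in both fractions of Hom mostly changed in opposite directions. Of 348 such genes 260 (74.7%) went opposite ways, 69 were higher in both fractions against 22.0 expected from independent calls, and 19 were lower in both against 8.12. Opposite pairs exceeded independent calls too: 160 were higher in nuclear and lower in total RNA against 20.3, and 100 the reverse against 8.80. Of all 5562 genes called in both fractions, whatever their fold, 2758 (49.6%) went opposite ways. The genes with the same direction included Apoe, the lipid carrier (log2 1.58 ± 0.03 in nuclear and 1.61 ± 0.05 in total RNA), and Jchain, the joining chain of antibodies (2.04 ± 0.07 and 2.76 ± 0.02). Kap (log2 -2.90 ± 0.05 and -1.56 ± 0.03) and the amino acid transaminase Bcat1 (-2.01 ± 0.04 and -1.60 ± 0.05) were lower in both. These 4 genes were chosen after their values were seen. Kap was highest in Nuclear_WT and Total_Het (14591 and 22941 CPM), as was Bcat1 (192 and 93.2 CPM), and both groups had high Y-linked counts. In Total_Hom, where Y-linked counts were high too, Kap was at 1829 CPM and Bcat1 at 23.7 CPM. A change apart from sex-dependent expression is therefore not shown for Kap and Bcat1. Across 14858 genes the nuclear and total log2 values of Hom against WT had a Pearson correlation of -0.337 but a Spearman correlation of -0.0129, and genes are not independent replicates.

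**Figure D3:**
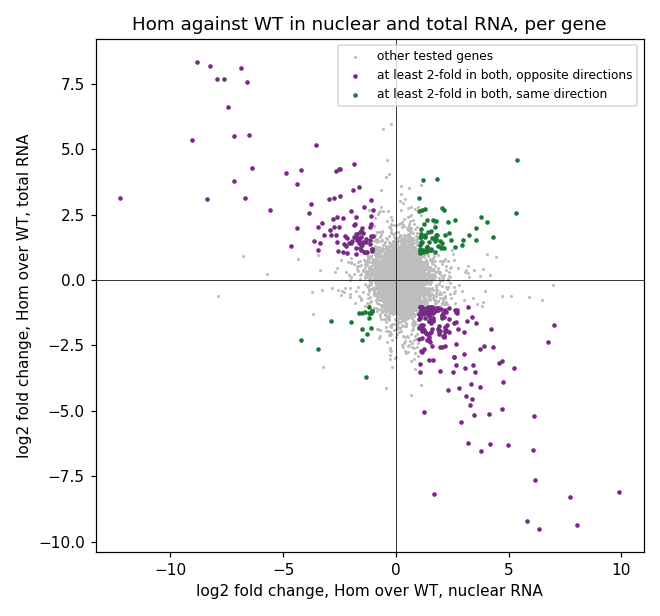
Log2 fold change of Hom over WT in nuclear RNA (horizontal axis) and total RNA (vertical axis), 1 point per gene tested in both fractions. Of 348 genes that passed and changed by at least 2-fold in both, 260 lie in the quadrants of opposite sign (purple) and 88 in those of equal sign (green).

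The heterozygous libraries were compared with WT to see what a single mutant copy goes with. In nuclear RNA the Het libraries were rich in immune and interferon transcripts. Immune cell markers were higher in 21 of 22 with none (0) lower, also adjusted over the list alone (median log2 2.14, camera adjusted p = 2.12e-19, adjusted p = 0.0163 with an estimated correlation), among them Lyz2 (log2 3.05 ± 0.04) and the antigen presentation chain Cd74 (1.28 ± 0.02). All 31 interferon response genes were higher, also adjusted over the list alone (median log2 0.73, camera adjusted p = 1.37e-09, adjusted p = 0.0174 with an estimated correlation), for example Iigp1 (log2 2.39 ± 0.11). Jchain rose from 4.99 ± 0.798 to 382 ± 6.26 CPM (SD, n = 3; log2 6.28 ± 0.05 SE, edgeR adjusted p = 2.29e-94) and the chemokine Ccl8 from 0.247 ± 0.0992 to 14.2 ± 1.18 CPM (log2 5.86 ± 0.21).

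NF-kB and complement genes moved the same way in nuclear Het, with 24 of 25 higher and 1 lower and 21 of 23 higher and 1 lower, both also adjusted over the list alone (camera adjusted p = 5.30e-11 and 1.12e-16, adjusted p = 0.0163 and 0.0163 with an estimated correlation). C3 rose by log2 4.27 ± 0.04 and the injury marker Lcn2 by 4.39 ± 0.07. Extracellular matrix genes were higher in 27 of 30 and lower in 3, also adjusted over the list alone (camera adjusted p = 5.95e-08, adjusted p = 0.0266 with an estimated correlation). Heat shock genes were lower in 18 of 20 and higher in 1, and proximal tubule markers lower in 16 of 20 and higher in 2, both also adjusted over the list alone (camera adjusted p = 1.92e-09 and 4.27e-08, adjusted p = 0.0163 and 0.0266 with an estimated correlation). Respiratory chain genes were lower in 74 of 80 with none (0) higher, and ribosomal protein genes higher in 76 of 82 and lower in 1, both also adjusted over the list alone (camera adjusted p = 3.77e-12 and 6.67e-23, adjusted p = 0.240 and 0.149 with an estimated correlation). Podocyte markers were higher in 20 of 30 and lower in 4, or 20 and 5 adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.0864 with an estimated correlation). Nuclear Het had 4964 genes higher and 4793 lower than WT, 1412 and 360 by at least 2-fold. Scaling by library totals alone shifted the median log2 value of all genes by 0.18 and the share of higher calls from 50.9% to 75.9%. Nuclear_Het had high and Nuclear_WT low Xist.

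In total RNA the Het libraries held fewer transcripts of glomerular and distal cells and more of proximal tubule. Podocyte markers were lower in 24 of 30 and higher in 3, also adjusted over the list alone (median log2 -0.80, camera adjusted p = 1.02e-06, adjusted p = 0.0292 with an estimated correlation), with Podxl, the sialoprotein of the podocyte surface, at log2 -0.75 ± 0.03. Endothelial markers were lower in 16 of 19 and higher in 1, or 17 and 1 adjusted over the list alone (camera adjusted p = 3.11e-05, adjusted p = 0.0296 with an estimated correlation). Distal nephron markers were lower in 17 of 19 and higher in 2, and matrix genes lower in 25 of 30 and higher in 1, both also adjusted over the list alone (camera adjusted p = 1.02e-06 and 3.42e-08, adjusted p = 0.0292 and 0.0376 with an estimated correlation). Proximal tubule markers were higher in 14 of 20 and lower in 6, also adjusted over the list alone (median log2 0.26, camera adjusted p = 0.00493, adjusted p = 0.163 with an estimated correlation), led by Cyp4b1 (log2 3.86 ± 0.02). Ribosomal protein genes were lower in 73 of 82 and higher in 2, or 74 and 2 adjusted over the list alone (camera adjusted p = 5.24e-12, adjusted p = 0.130 with an estimated correlation).

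The largest rises in total Het were those of Slco1a1 (1.17 ± 0.0696 to 720 ± 16.4 CPM, SD, n = 3; log2 9.25 ± 0.05 SE), Uty (log2 8.57), Cyp2j13 (8.19), Kdm5d and Mpped1, the last pair with too few Total_WT counts for a fold. Uty held 4 counts in Total_WT, so its fold is uncertain too. The largest falls were those of Xist (log2 -9.13), Ugt1a2 (-8.81), Slc17a2 (-7.07), Serpina6 (-6.93) and Cyp4a14 (-6.86). In all, 4644 genes were higher and 4555 lower, 590 and 601 by at least 2-fold, and Total_Het had low and Total_WT high Xist. Scaling by library totals alone shifted the median log2 value of all genes by -0.18 and the share of higher calls from 50.5% to 24.5%. With the deposited column of Total_WT replicate 1 the total was 7044 genes in place of 9199, and Uty (log2 2.48) and Kdm5d (2.44) no longer passed. The nuclear-to-total ratio of Het against WT had 5820 genes higher and 5073 lower, 2577 and 1200 by at least 2-fold, with Xist (log2 19.04) and Ugt1a2 (15.38) the largest rises and Slco1a1 (-13.77) among the 5 largest falls. In that ratio all 22 immune markers were higher, also adjusted over the list alone (camera adjusted p = 1.84e-09, adjusted p = 0.00417 with an estimated correlation), and Nup93 gave log2 0.62 ± 0.10 (edgeR adjusted p = 1.28e-08). With library totals alone the median of all genes in that ratio shifted by 0.36 and the share of higher calls went from 53.4% to 78.6%.

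Het and Hom changes were compared with each other across genes, both against the same WT libraries. In nuclear RNA 2996 genes were higher in both genotypes against 1318 expected from independent lists, and 3478 were lower in both against 1333. In total RNA 2072 were higher in both against 1421, and 2115 were lower in both against 1414. The correlation across genes was 0.773 in nuclear RNA, beside 0.509 simulated for unchanged groups that share the WT libraries, and 0.603 in total RNA, beside 0.485. In total RNA the Spearman correlation was 0.309, the deposited column of Total_WT replicate 1 gave 0.421, and 58.9% of genes had the same sign. The nuclear Spearman correlation was 0.785. The covariances were 0.454 and 0.329, beside 0.0125 and 0.0101 simulated. The 3 WT libraries of a fraction were not split, since 1 part would hold a single library, so part of any excess may come from the shared controls. In each fraction Het and Hom also had the same Xist status and WT the other, and the simulations held no such difference. A difference in sex from WT could therefore also give this overlap and correlation.

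Hom was compared with Het within each fraction, where the libraries had the same Xist status. In nuclear RNA, Hom lacked most of the immune signal of Het. Immune cell markers were lower in 21 of 22 with none (0) higher, also adjusted over the list alone (median log2 -1.67, camera adjusted p = 3.98e-34, adjusted p = 0.00146 with an estimated correlation), among them Cd74 (log2 -1.74 ± 0.02). Slpi, a leukocyte protease inhibitor, fell from 41.8 ± 2.24 to 1.34 ± 0.337 CPM (SD, n = 3; log2 -4.98 ± 0.11 SE, edgeR adjusted p = 1.44e-59), Lcn2 from 89.8 ± 2.20 to 6.70 ± 0.704 CPM (log2 -3.74 ± 0.06) and Jchain by log2 -4.23 ± 0.04. Apoa4, an apolipoprotein, rose from 4.95 ± 0.987 to 23.5 ± 1.40 CPM (log2 2.23 ± 0.09) and the mitochondrial carrier Slc25a25 from 33.5 ± 0.897 to 148 ± 4.09 CPM (log2 2.14 ± 0.04). In Nuclear_WT, Slpi, Lcn2, Apoa4 and Slc25a25 stood at 0.766, 4.31, 13.8 and 154 CPM.

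Interferon genes were lower in nuclear Hom than in Het in 28 of 31 and higher in 1, and complement genes lower in 22 of 23 with none (0) higher, both also adjusted over the list alone (camera adjusted p = 4.65e-14 and 2.65e-28, adjusted p = 0.00515 and 0.00140 with an estimated correlation). Proximal tubule markers were higher in 17 of 20 and lower in 2, or 18 and 2 adjusted over the list alone (median log2 0.27, camera adjusted p = 1.62e-09, adjusted p = 0.0208 with an estimated correlation), for example Pck1, a gluconeogenic enzyme (log2 1.37 ± 0.02). Respiratory chain genes were higher in 77 of 80 with none (0) lower, also adjusted over the list alone (camera adjusted p = 9.39e-27, adjusted p = 0.126 with an estimated correlation). Gene list tests of Hom against Het, of the Het ratio and of nuclear against total RNA were added after seeing the data. Nuclear Hom had 3236 genes higher and 3293 lower than Het, 126 and 731 by at least 2-fold, and with library totals alone the share of higher calls went from 49.6% to 33.6%.

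In total RNA, endothelial and podocyte marker lists were called higher in Hom than in Het. Endothelial markers were higher in 18 of 19 with none (0) lower, and podocyte markers higher in 22 of 30 and lower in 4, both also adjusted over the list alone (median log2 0.68 and 0.51, camera adjusted p = 3.62e-08 and 0.000335, adjusted p = 0.0224 and 0.0340 with an estimated correlation). Synpo, an actin-binding protein of podocytes, gave log2 1.07 ± 0.04 and Podxl 0.84 ± 0.03. Acsm3, a medium-chain acyl-CoA synthetase, fell from 699 ± 5.81 to 3.78 ± 0.334 CPM (SD, n = 3; log2 -7.53 ± 0.04 SE, edgeR adjusted p = 2.50e-163) and Inmt, a methyltransferase, from 602 ± 6.94 to 32.4 ± 1.09 CPM (log2 -4.21 ± 0.03). Cyp4a14 rose from 3.58 ± 0.615 to 273 ± 6.24 CPM (log2 6.26 ± 0.04). In Total_WT, Acsm3, Inmt and Cyp4a14 stood at 3.23, 16.7 and 414 CPM, so Hom lay nearer to WT than Het did. Acsm3 and Inmt were also high in Nuclear_WT (309 and 593 CPM), which had high Y-linked counts as Total_Het did. These changes are therefore not shown to be free of sex-dependent expression.

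Parietal epithelial markers were higher in total Hom than in Het in 13 of 14 and lower in 1, and immediate early genes higher in 20 of 27 and lower in 1, both also adjusted over the list alone (camera adjusted p = 5.09e-05 and 1.11e-05, adjusted p = 0.0340 and 0.0340 with an estimated correlation). Nuclear transport receptors and Ran cycle genes were lower in 22 of 29 and higher in 3, also adjusted over the list alone (median log2 -0.27, camera adjusted p = 0.000844, adjusted p = 0.0344 with an estimated correlation), among them Tnpo1 (log2 -0.54 ± 0.03) and Ran (-0.46 ± 0.03). Ribosomal protein genes were higher in 77 of 82 and lower in 2, also adjusted over the list alone (median log2 0.66, camera adjusted p = 1.45e-24, adjusted p = 0.0549 with an estimated correlation). Of 216 genes that changed by at least 2-fold between Hom and Het in both fractions, 154 (71.3%) went opposite ways, 22 were higher in both against 5.48 expected from independent calls, and 40 were lower in both against 23.1. Opposite pairs exceeded independent calls too: 23 were higher in nuclear and lower in total RNA against 4.02, and 131 the reverse against 31.6. In all, 4949 genes were higher and 5138 lower in total Hom than in Het, 786 and 574 by at least 2-fold. Scaling by library totals alone shifted the median log2 value of all genes by 0.15 and the share of higher calls from 49.1% to 68.3%.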

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

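The tests of retention specific to Hom, of exchanged WT labels, of the column sum and of deeper sequencing were chosen only after the result was seen.

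Genes changed at least 2-fold by Hom in both fractions went opposite ways in nuclear and total RNA in 260 of 348 cases, in a design where Xist status also turns between the fractions. Without the 2-fold limit 2758 of 5562 genes called in both (49.6%) did so. In Het against WT 485 of 548 genes (88.5%) went opposite ways at 2-fold, and 5878 of 6818 (86.2%) without that limit. The split of the 6 groups by Xist level held 39.4% of the variance between group means with sex-linked genes left out, the highest of 10 splits (next 31.1%, RNA fraction 14.0%), and of 255 opposite genes 228 (89.4%) had the same sign in Nuclear_Het minus Total_Het, so a difference in sex between the libraries is a candidate explanation. A difference in Xist status cannot account for Hom against Het, where that status was equal within each fraction. There 154 of 216 genes (71.3%) at 2-fold, and 3409 of 4803 called genes (71.0%), also went opposite ways. Equal Xist status does not show that these groups were alike in other sex-dependent expression. Slco1a1, which followed Xist status over the groups, was lower in Hom than in Het in nuclear (10.4 to 0.446 CPM) and total RNA (720 to 47.3 CPM). Cyp7b1 was too (10.9 to 3.30 and 374 to 64.8 CPM), but Igf2 was not lower (195 to 256 and 4.98 to 5.63 CPM). Uty also differed in nuclear RNA (log2 -3.30, edgeR adjusted p = 6.92e-07), at 0.671 and 0.0613 CPM. Retention of RNA specific to Hom is argued against as the whole cause, because it would leave Het at the WT ratio. Over these 255 genes the median ratio change of Hom over Het was -0.0216 of that of Hom over WT (SD over genes 0.451, leave-one-out -0.0331 to -0.00891), where 1 would be needed. In 25 of them the share was at least 0.5, and for these it stays open. An exchange of the labels of the WT nuclear and WT total libraries would make 6 of 6 groups carry the sex of their RNA fraction, but it cannot be told apart from other assignments of animals, since no other value identifies them. An effect of the genotype stays open and was not separable from sex in any single comparison with WT. Xist status turns between the fractions, so a sex difference alone would not move a gene the same way in both. If the labels hold, an equal sex effect in both fractions does not give the 69 genes of Hom higher in both and 19 lower. Their excess over independent calls (22.0 and 8.12) adds nothing, since opposite pairs exceeded theirs by more (160 against 20.3, 100 against 8.80). In Het 58 were higher and 5 lower in both, against 46.6 and 13.7. Other differences between the animals, sex-dependent expression among them, stay open for these genes. Kap, for example, was at 22941 CPM in Total_Het and 1829 CPM in Total_Hom.

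Nuclear-retained RNAs were at most slightly higher in the nuclear libraries. In the pairs of groups with equal Xist status the list's median log2 ratio was 0.14 (Nuclear_Hom over Total_WT, SD over members 0.25) and 0.08 (Nuclear_WT over Total_Het, SD 0.37), and 0.14 and 0.08 for the 26 members without Xist and Tsix, which is consistent with little nuclear enrichment if the labels hold. Within genotypes it was 0.13 in WT, 0.22 in Het and -0.08 in Hom. Malat1 and Neat1 were at log2 0.22 and 0.32 in Het and -0.05 and 0.07 in Hom, and lower in nuclear RNA of WT, and the WT values turn sign if the WT labels are exchanged. At equal Xist status they were at -0.21 and 0.13 (Nuclear_WT over Total_Het) and at -0.16 and 0.001 (Nuclear_Hom over Total_WT). The median rose by at most 0.0159 from the WT comparison to a pair of equal Xist status. With the WT labels exchanged these pairs would hold 1 fraction each, so a sex difference that hides the enrichment cannot be told apart. No biological explanation was tested.

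Subtracting the sum of the 9 nuclear columns took 181 M (mega) counts from the Total_WT replicate 1 column, and these entered this library only in the alternative with the deposited column. Of its genes 0 lay below the sum of the 9 nuclear columns, while 2608 lay below the sum of the other 8 total columns, so a column that holds the sum of the 9 nuclear columns and 1 further library is a candidate explanation. Deeper sequencing of 1 library is argued against: scaled to the total of this column, replicates 2 and 3 lay below the nuclear sum in 2871 and 2890 of 14652 genes with at least 100 nuclear counts, and the column itself in 0. The Y-linked genes stood at 48.5 CPM in the deposited column and 0.473 CPM in the remainder.

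The interaction test of genotype and RNA fraction found that Hom differed from WT unequally in nuclear and total RNA for 8643 genes, and for Nup93 (log2 0.32). It set high-Xist Nuclear_Hom and Total_WT libraries against low-Xist Nuclear_WT and Total_Hom libraries, so genotype was not separable from sex here. The same test gave log2 differences of 17.98 for Xist, 13.80 for Slc17a2, 11.32 for Hdc, 10.43 for Igf2, 8.64 for Akr1c20, 8.62 for Rdh19, 7.75 for Fabp1, 7.56 for Prlr and 7.15 for Ugt1a2. It gave -17.14 for Uty, -15.60 for Ddx3y, -15.30 for Eif2s3y, -14.38 for Slco1a1, -14.07 for Cyp2j13, -12.67 for Pzp, -12.03 for Slc7a13 and -10.66 for Ugt2b37, and fitted values that depend on the prior count of -16.41 for Kdm5d and -14.95 for Mpped1. Uty held 4 counts in Nuclear_Hom and 4 in Total_WT, so its value leans on the prior count as well. For Het the test found 10893 genes and a log2 difference of 0.62 for Nup93, 19.04 for Xist, 15.38 for Ugt1a2, 13.14 for Slc17a2, 11.76 for Hdc, 11.10 for Cyp4a14, -14.11 for Uty, -13.90 for Ddx3y and -13.77 for Slco1a1. The values of -15.12 for Mpped1 and -13.97 for Kdm5d in Het depend on the prior count. The Het test set high against low Xist in the same way.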

How the results depend on the processing

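The use of the deposited Total_WT replicate 1 column and the removal of Rn45s were tests chosen only after the result was seen. Of 390 alternative values for the main results, 361 were scored the same and 0 reversed. Another 13 lost a call or fell, 9 gained one or rose, and 7 correlations moved beyond their jackknife SE. Counts of genes or lists were scored the same within 1.5 times the main count, and correlations within their jackknife SE. Nup93 was scored by its side of the threshold and its sign. A count could not be scored as reversed, and a shift in its share of higher calls was not scored. All 144 gene counts stayed within 1.5 times the main count, and of 1329 alternatives for named genes 1319 kept their call. The cause was not tested for the changes below except where a setting itself removes libraries or counts.

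List counts for nuclear Hom, total Hom, nuclear Het and total Het against WT and for the Hom ratio were 17, 14, 20, 15 and 5. With an estimated correlation they were 2, 0, 8, 4 and 0, and with fry, which makes no comparison with other genes, 28, 32, 35, 33 and 31. The Hom ratio had 3 lists with the deposited column.

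Nup93 in nuclear Hom against Het (-0.16) did not pass with DESeq2 (-0.16), RLE size factors (-0.15) or no filter (-0.15). Leaving out 1 library gave -0.24 (without Nuclear_Hom replicate 2) to -0.12, with the call lost without Nuclear_Het replicate 1 (-0.17) or 3 (-0.13) and without Nuclear_Hom replicate 1 (-0.13) or 3 (-0.12). Library totals alone made Nup93 pass in total Het against WT (-0.29) and in total Hom against Het (0.30), where it also passed at a mean of at least 5 CPM (0.18) and without Total_Hom replicate 3 (0.17), over a leave-one-out range of 0.13 to 0.17.

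The correlation of Het and Hom changes in nuclear RNA was 0.827 at a mean of at least 5 CPM (0.773 in the report, jackknife SE 0.0196, leave-one-out 0.762 to 0.783). In total RNA (0.603, SE 0.0172, 0.593 to 0.611) it was 0.576 at 5 CPM, 0.309 by Spearman and 0.421 with the deposited column. The correlation of nuclear and total Hom changes (-0.337, SE 0.0124, -0.341 to -0.327) was -0.409, -0.0129 and -0.197 in the same order.

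With the deposited column 9 named-gene calls were lost, all of genes higher in Nuclear_WT than in Total_WT, whose nuclear counts that column adds. Replicate numbers did not pair the libraries: of 45 same-number pairs in 15 pairs of groups, 3 had r over 0.1 (range -0.128 to 0.22), and 18 correlated best with their own number. The replicate block gave 8242 genes in nuclear and 9249 in total Hom against WT and 8720 in the ratio, and changed no call of a named gene. Of simulated 1.1-fold changes in nuclear RNA, 14% were recovered, with far fewer genes changed than were called in the data.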

Other observations

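No test in this part was chosen only after the result was seen; the genes named here were chosen after their values were seen.

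In nuclear RNA, Mzb1 and C4b were higher in Het than in the other genotypes. Mzb1, a plasma cell chaperone, stood at 0.808 ± 0.272 CPM in Nuclear_WT, 20.7 ± 0.632 CPM in Nuclear_Het and 2.10 ± 0.317 CPM in Nuclear_Hom (SD, n = 3). The complement gene C4b was at 10.97 ± 0.543, 86.2 ± 4.34 and 10.6 ± 1.37 CPM. In total RNA both mutant genotypes lay above WT: Mzb1 at 2.84 ± 0.555, 17.1 ± 0.50 and 13.9 ± 0.0654 CPM and C4b at 10.8 ± 0.728, 32.8 ± 0.920 and 37.3 ± 0.681 CPM in WT, Het and Hom. S100a9, a granulocyte protein, was at 3.0 ± 0.279, 7.66 ± 0.484 and 19.5 ± 1.42 CPM in the same order.

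Genes lower in Hom than in WT in both fractions included Mfsd2a, a lipid transporter (log2 -1.51 ± 0.07 in nuclear and -2.31 ± 0.07 in total RNA), Cish, a cytokine signalling inhibitor (-1.62 ± 0.04 and -1.27 ± 0.04), and the organic cation transporter Slc22a2 (-1.14 ± 0.03 and -1.25 ± 0.03). Slc22a2 was highest in Nuclear_WT and Total_Het (295 and 395 CPM), groups with high Y-linked counts, and lowest in Total_Hom (50.5 CPM), where they were high too. Mfsd2a and Cish were higher in Total_WT (37.5 and 108 CPM) than in Total_Het (34.6 and 69.1 CPM). Aldh3a1, an aldehyde dehydrogenase, was higher in both fractions of Hom (1.66 ± 0.18 and 2.28 ± 0.13).

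Genes near Nup93 could carry strain variants linked to the edited allele. Of 200 tested neighbours of Nup93, 0 changed at least 2-fold in the same direction in both fractions of Hom against WT, which allows a share of up to 1.5%, against 87 of 14218 genes elsewhere (0.612%). Linkage to the Nup93 locus had a one-sided p of 1 for a higher share (Fisher's exact test) and 0.296 for a lower one, and it cannot be told apart at this number of neighbours.

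Other splits of the same libraries into groups of 3 were fitted for each count. For the Hom and Het ratios, 1 of 100 drawn splits, the real one, gave as many genes (8643 and 10893). The others gave at most 4515 and 6052, with a median of 0 in both ratios. They mixed libraries of unlike groups, which widens the spread within a group, so this ranking does not decide on chance. Chance differences between animals, which the labels do not identify, stay open as well. For the gene lists of the Hom ratio, 62 of 100 splits gave at least the real 5, with 19 as the highest other and a median of 9, so chance cannot be excluded. The 3-against-3 comparisons have 10 splits, too few for a share under 0.05: the highest other gene count was 0 against real counts of 8213, 9757, 6529, 9277, 9199, 10087 and 9515. The highest other list counts were 9 against 17 in nuclear Hom, 7 against 14 in total Hom, 13 against 20 in nuclear Het and 11 against 15 in total Het.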
